A study of Caenorhabditis elegans with 2 samples.

How the data were processed

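Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used, per the labels, to map where the protein of ztf-4, a gene named as a zinc finger transcription factor, lies on the chromosomes of the nematode Caenorhabditis elegans. The material was whole animals of pooled sexes at the L1 larval stage, from strain OP322, which carries an insertion that encodes ZTF-4 fused to the green fluorescent protein eGFP. The labels name eGFP-ztf-4 as the precipitated protein and ztf-4 in the antibody field, and the antibody itself is not given in the sources used here. The extraction protocol is likewise not given in the sources used here. The labels give 1 group with 2 biological replicates, and the control that entered the authors' calling was not analysed here.

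Per the records deposited with the files, the authors called regions against a control in replicate 1, in replicate 2 and on the pooled alignments of both replicates, each as a relaxed list of peaks and background that served as input to the irreproducible discovery rate (IDR) procedure, which keeps regions whose ranks recur between replicates. A thresholded list of IDR peaks was then derived from those 3 lists. All lists were deposited for assemblies ce10 and ce11. The aligner, the peak caller and the IDR cutoff are not given in the sources used here. The signal value of each region, which the authors deposited in the seventh column, is the caller's own height of that region. Its pooled values lie near the sum of both replicates' values, so signals were ranked only within a list. The deposited −log10 q value was tied at its maximum for 1576 of the 1898 IDR peaks in ce11 and was used only to describe the lists. The files hold no read counts, so the depth is unknown, and every interval given for a share of peaks or genes is an exact Clopper-Pearson 95% interval. Where a count is 0, the share it allows is instead given as 3 counts of the total, which is somewhat below the upper bound of the exact 95% interval. Both cover counting error only.

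Coordinates were used as deposited in ce11, printed from base 1, and annotated with Ensembl release 115 on WBcel235, the same assembly under another name. All region ends fell within the reference chromosome lengths, and 0 regions lay outside the 6 nuclear chromosomes. The ce10 lists were used without annotation, because the reference was not of that build. The position of a peak is its summit. A promoter window runs from 1000 bp upstream to 200 bp downstream of the annotated 5' end of a protein-coding gene, which for trans-spliced worm genes can lie downstream of the true start of transcription. Where annotations overlapped, a summit was assigned first to a coding exon, then to a UTR, then to an exon of a non-coding gene or pseudogene (piRNA genes not counted), then to an intron.

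Agreement between replicates was measured as the share of the N strongest regions of replicate 1 with a summit of the N strongest of replicate 2 within 100 bp, with N set to the number of IDR peaks. This share, the promoter share and the share of non-coding genes with a summit within 200 bp were set against 1000 random circular shifts of all summits within their chromosomes (1-sided permutation tests, smallest possible p 0.001). Shares of X-chromosomal peaks were compared with the share of protein-coding genes by exact 2-sided binomial tests. The median log2 signal of promoter and other peaks was compared by 100000 permutations (2-sided, smallest possible p 1e-05), with bootstrap intervals from 2000 draws. Each of 36 gene lists was tested by Fisher's exact test (2-sided) against all other protein-coding genes for having a promoter peak, with Benjamini-Hochberg adjustment over the lists. Each of 2080 6-mers, counted together with its reverse complement, was tested for presence within 50 bp of the summit against windows centred 300 bp to each side, by an exact McNemar test against each side of which the larger p was kept, with Benjamini-Hochberg adjustment. Neighbouring genes can share a peak and peaks are not replicates, so these p-values describe this peak set and not the spread between animals. Results from each replicate alone are given for that reason.

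The groups, tests, gene lists and most alternatives were fixed before the data were examined. So was the rule for named items, which takes the 20 IDR peaks of highest signal with the nearest gene and any other gene that holds the summit, up to 4 members per gene list with the strongest promoter peaks, ztf-4 and unc-119 whatever their values, the 5 enriched 6-mers with the largest ratio among those present in at least 5% of peaks, and any mitochondrial peaks. The alternatives were each replicate alone, the stronger peaks only, the pooled list, other promoter windows, other rules for giving peaks to genes, other overlap criteria, the ce10 lists, other backgrounds and windows for 6-mers, and the genome length share for X. Giving each peak to its nearest gene also used the peaks outside promoter windows, so it is a different measure from having a promoter peak. Leaving out X and matching the 6-mer background on GC content were added after the data were seen.

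The tests were first run on simulated data. Random summits passed the promoter test in 4% of 100 simulations, and summits of which 5% had been moved to gene 5' ends passed in 100%. Of 5 gene lists given 4 times the usual share of hits, 82.2% were called, while 2% of simulations without an effect called any list. These list simulations drew each gene's hit independently. In the data neighbouring genes can share a peak, so the 2% need not hold for them. Planted tRNA genes were called in 100% of 20 simulations, and 99% of 6-mers planted in 5% of windows were called. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.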

Results

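ZTF-4 occupancy was profiled by ChIP-seq in L1 larvae of C. elegans that carry an eGFP-tagged ztf-4 transgene, in 1 group of 2 biological replicates. The deposited relaxed lists in assembly ce11 held 27643 regions for replicate 1, 27140 for replicate 2 and 23044 for the pooled replicates, and 1898 regions passed the authors' IDR threshold. In ce10 the threshold kept 1878. The IDR peaks were exactly the 1898 regions of highest signal in the pooled list, with signals from 49.6 to 904. Most IDR peaks (91.4%) had the common width of 350 bp. The depth is unknown, and no mock or input library was analysed here, so a peak is a place where the authors' caller found recovery above its control.

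The strongest sites were the same in both replicates. The peak upstream of rpl-3, which encodes a protein of the large ribosomal subunit, ranked 1 in replicate 1 (signal 456), 1 in replicate 2 (signal 453) and 1 in the pooled list (signal 904). The peaks at cdc-48.1, a protein-unfolding ATPase, and at tasp-1 also held ranks 2 and 3 in all of these lists. All 20 strongest IDR peaks ranked 26 or better in replicate 1 and 27 or better in replicate 2. Over the 1898 strongest regions per replicate, 1158 of replicate 1 (61.0%, 58.8 to 63.2) had a counterpart in replicate 2, against a mean of 0.393% for shifted summits (SD 0.145, 1-sided permutation p = 0.001). Of the IDR peaks, 1767 (93.1%) had a matching region in both relaxed replicate lists, and across those peaks the signals of the replicates correlated with Spearman's rho 0.572 and Pearson's r 0.679 on the log2 scale. Peaks are not independent replicates, so no p was attached to these correlations. The IDR procedure favours regions that recur between replicates, so the 93.1% and the correlations are not independent measures of agreement. Among all regions of the relaxed lists the share of replicate 1 with a counterpart in replicate 2 was 27.3%, against 5.50% for shifted summits.

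**Figure D1:**
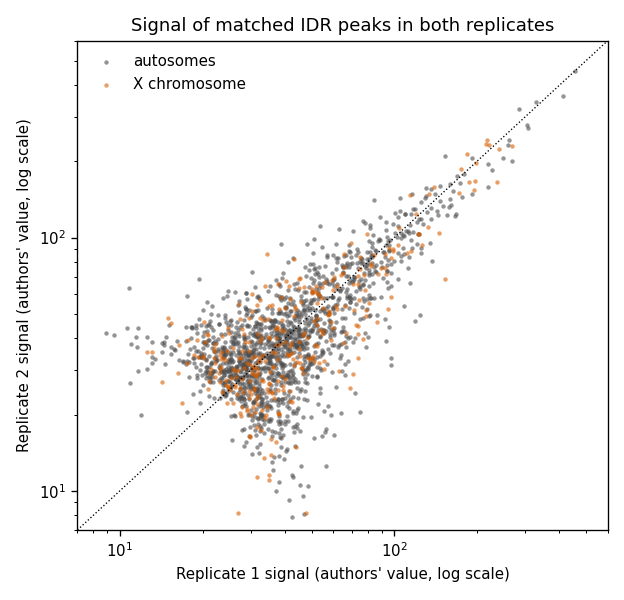
Signal of the 1767 IDR peaks matched in both replicates, with replicate 1 on the horizontal and replicate 2 on the vertical axis, both in the authors' signal units on log scales, one point per peak and the dotted line marking equal values. Peaks on X are orange and those on autosomes grey. The strongest peaks lie near the line, while weaker peaks scatter more widely (Spearman's rho 0.572 over all).

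ZTF-4 peaks lay mostly outside coding sequence and often just upstream of genes. Of the 1898 IDR summits, 936 (49.3%, 47.0 to 51.6) fell in a promoter window of a protein-coding gene, against 21.1% (SD 1.00) for shifted summits (permutation p = 0.001). With the peaks of replicate 1 alone the share was 45.6%, and with those of replicate 2 alone 49.4%. Among the 1060 summits within 1000 bp of the nearest gene 5' end, 80.8% were upstream of it, with a median position of −175.5 bp. The 100 bp bin from −200 to −100 bp held 11.7% of all summits, against 1.90% (SD 0.331) for shifted ones. Intergenic sequence held 61.0% of the summits against 34.3% after shifting, 5' UTRs 3.00% against 1.42%, and exons of non-coding genes or pseudogenes 9.06% against 2.99%. Coding exons held 4.37% against 24.6%, introns 20.9% against 33.3%, and 3' UTRs 1.63% against 3.38%. Each of these 6 shares lay outside the range of the shifted values (2-sided permutation p = 0.002, the smallest the shifts allow). In a narrow window of 300 bp upstream to 100 bp downstream the promoter share was 31.3% against 7.57%.

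**Figure D2:**
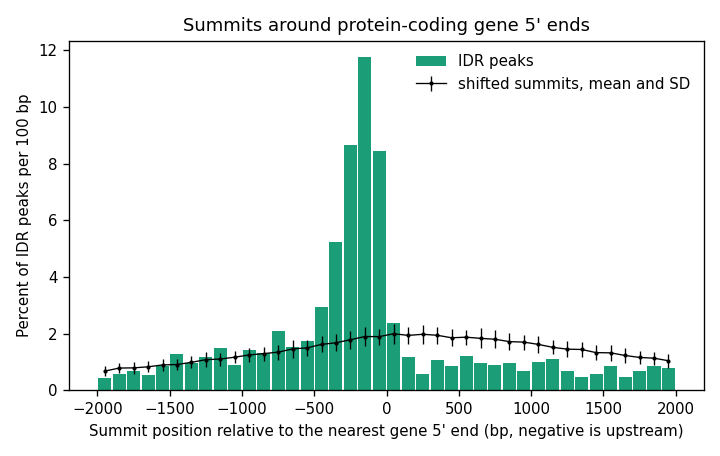
Percent of the 1898 IDR summits (green bars) per 100 bp by position relative to the nearest protein-coding gene 5' end in bp, negative values being upstream, with the mean and SD of shifted summits as black points. The highest bar, from −200 to −100 bp, holds 11.7% of the peaks, against 1.90% for shifted summits.

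Peaks in promoters were somewhat higher than peaks elsewhere. Their median signal was 77.1, against 68.2 for the other 962 peaks, a difference of 0.18 on the log2 scale (bootstrap interval 0.09 to 0.24, permutation p = 1e-05, the smallest possible). The difference was 0.13 in replicate 1 alone and 0.17 in replicate 2 alone. Among the 949 stronger IDR peaks it was 0.04 (p = 0.357), and, again by permutation, with a promoter window of 2000 bp upstream to 500 bp downstream it was 0.09 (p = 0.0099). The stronger peaks were picked by this same signal, which by itself can narrow the difference, so the 0.04 does not argue against it.

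Of the 20 strongest peaks, 12 lay in promoter windows and 8 lay on chromosome III. Ribosomal protein genes stood out among them. The rpl-3 peak covered III:3867452-3867698, intergenic, with its summit at −284 bp from the gene's 5' end. The peaks of rpl-15 (IV:654806-655045, signal 583), rpl-35 (III:7854573-7854820, signal 578) and rps-1 (III:4475554-4475770, signal 501) had their summits at −350, −435 and −255 bp from the 5' ends of these genes, negative positions being upstream, and the rps-1 summit fell in an exon of the non-coding gene F56F3.10. A peak of signal 606 at IV:4749946-4750198 lay between Y17G9B.5 and the ribosomal protein gene rpl-20, which are transcribed away from each other. Further peaks among the 20 lay in the promoter windows of cdc-48.1 (II:10563448-10563694, signal 779), tasp-1 (III:10759116-10759388, signal 670) and the cytochrome c oxidase gene cox-5A (III:12905096-12905313, signal 486). Others lay in those of nspc-17 on X, egg-5 on I, tag-340 on III and cbp-1, which encodes a histone acetyltransferase (III:9765505-9765756, signal 418). The summit nearest to egg-5, at −578 bp, lay within 200 bp of the spliced leader RNA gene sls-2.4 and the non-coding gene R12E2.18. The tag-340 summit lay in an exon of the non-coding gene F26F4.14.

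The other 8 of the 20 lay outside promoter windows, and 6 of these were on X. The strongest was intergenic at X:11094030-11094343 (signal 499), 3961 bp downstream of the 5' end of W02H3.3 and beyond that gene. A second lay at X:8036294-8036540 (signal 462), at −4922 bp from the 5' end of xol-1, the X-linked switch gene of sex determination. The remaining X peaks had K02D3.1, F20B6.9, cest-16 and ZK899.6 as nearest genes, with signals of 454, 428, 402 and 400, and the summit nearest to cest-16 fell in an intron of mom-1. On autosomes, a peak of signal 437 lay in an intron of Y111B2A.12 on III, and a peak of signal 398 near ins-13 on II had its summit in the spliced leader RNA gene sls-2.2 and in the non-coding gene C17C3.23.

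Peaks were unevenly spread over chromosomes. X held 359 of the 1898 peaks (18.9%, 17.2 to 20.8), against 13.7% of protein-coding genes (exact binomial p = 2.39e-10), and the share was 18.8% in replicate 1 alone and 17.7% in replicate 2 alone. Against the 17.7% of the genome length that X makes up, the share did not differ detectably in this number of peaks (exact binomial p = 0.157). Over the 6 chromosomes, III held 17.97% of peaks against 13.2% of genes (adjusted exact p = 1.02e-08) and I held 16.4% (14.8 to 18.2) against 14.4% (adjusted exact p = 0.0195). The genome length share of I, 15.03%, lies within that interval, so its excess, like that of X, depends on the reference, while that of III (13.7%) lies below the interval of its peak share (16.3 to 19.8). Chromosome V, with 25% of genes, held 14.8% of peaks (adjusted exact p = 1.52e-26), while II and IV did not pass the test (adjusted exact p = 0.164 and 0.577). In both replicates alone the shares of I, III and X were above their gene shares and that of V below it (III 17.8% and 18.2%, V 14.9% and 14.8%). Peaks on X were in promoter windows in 41.8% of cases and those on autosomes in 51.1% (Fisher's exact p = 0.00155), but shifted summits also gave a lower share on X (17.6%, SD 1.94) than on autosomes (21.98%, SD 1.13), so that the excess was 2.38-fold and 2.32-fold.

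Genes of cytosolic ribosomal proteins, translation factors, respiratory chain subunits, chaperones and proteasome subunits carried promoter peaks far more often than other genes, while those of aminoacyl-tRNA synthetases and mitochondrial ribosomal proteins did not pass the test. In all, 1213 of 19973 protein-coding genes (6.07%) had a promoter peak, and 287 of the 936 promoter peaks lay in the windows of 2 or more genes. Of 36 gene lists, 12 had a higher share than the other genes and 3 a lower one by Fisher's exact test at an adjusted p under 0.05. Cytosolic ribosomal proteins had peaks at 47 of 81 genes (58.0%, 46.5 to 68.9, odds ratio 22.2, adjusted exact p = 1.04e-34, range over settings 1.04e-34 to 0.000829), and the share was 54.3% with either replicate alone. This odds ratio was the highest of the 36 lists, but it fell to 10.9 in the narrow promoter window, to 5.72 with each peak given to the nearest gene and to 4.89 with peaks shared between genes left out. In the last 2 settings other lists had higher ones, such as heterochronic genes (11.99) in the first and autophagy genes (6.72) in the second. The nearest-gene setting also counted peaks outside promoter windows, at 1544 genes in all. Its odds ratios, here and below, therefore do not describe promoter peaks alone. Of the 15 calls, 13 were also made with replicate 1 alone and 14 with replicate 2 alone. The peaks of rpl-3, rpl-20, rpl-15 and rpl-35 were the highest. Translation factors had peaks at 14 of 42 (33.3%, odds ratio 7.81, adjusted exact p = 6.58e-07), among them iff-2 (signal 377), eif-3.C (246), eef-2 (191) and eef-1A.1 (184). Respiratory chain subunits had peaks at 14 of 40 genes (35.0%, odds ratio 8.41, adjusted exact p = 4.05e-07), with cox-5A, cox-5B (230), atp-1 (208) and cox-6A (124) at the top. With each peak given to the nearest gene the odds ratios of these 2 lists were 4.80 and 5.15.

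Chaperones had promoter peaks at 19 of 59 genes (32.2%, odds ratio 7.45, adjusted exact p = 1.09e-08) and proteasome subunits at 10 of 33 (30.3%, odds ratio 6.77, adjusted exact p = 8.65e-05). The chaperone gene hsp-110 and the proteasome gene rpn-3 share a peak of signal 293 at III:8447065-8447254. It was followed by those of hsp-60 (275), cct-1 (216) and dnj-13 (213) among chaperones, and of pas-4 (95.5), pbs-1 (86.4) and rpn-11 (82.5) in the proteasome. With each peak given to the nearest gene the odds ratios fell to 2.75 and 3.83, and that of the proteasome was 4.19 without replicate 1. With peaks in the windows of 2 or more genes left out, neither the chaperones (adjusted exact p = 0.26, range over settings 1.32e-09 to 0.26) nor the proteasome (adjusted exact p = 0.457, range 3.78e-05 to 0.457) passed the test.

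Lists of regulators of chromosomes and RNA were also enriched. Chromatin regulators had promoter peaks at 10 of 40 genes (25%, adjusted exact p = 0.000417), led by cbp-1, set-16 (298), htz-1 (160) and swsn-3 (103.9). Cell cycle and DNA replication genes also stood at 10 of 40 (25%, adjusted exact p = 0.000417). Their strongest peaks were at lin-54 (318), lin-53 (216), lin-9 (194) and efl-1 (125), of which those of lin-54, lin-53 and efl-1 also lay in the windows of rpl-12, nra-2 and fbxa-90. Splicing factors had peaks at 10 of 44 (22.7%, adjusted exact p = 0.000848), with rsp-1 and rsp-2 sharing a peak of signal 125, followed by prp-40 (122) and snr-4 (119.005). Autophagy and lysosome genes reached 6 of 28 (21.4%, adjusted exact p = 0.0176), led by lgg-2 (337), lgg-1 (233), rab-7 (118) and atg-18 (69.9). Splicing factors and cell cycle genes did not pass with peaks shared between genes left out (adjusted exact p = 0.755 and 0.277) or with each peak given to the nearest gene (0.27 and 0.0718), with ranges over settings of 0.000166 to 0.755 and 0.000197 to 0.277. The autophagy call ended among the stronger peaks (adjusted exact p = 0.178, range over settings 4.27e-05 to 0.178), and the odds ratio of chromatin regulators ran from 2.99 with the nearest gene to 8.31 among the stronger peaks.

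For 3 lists the call was lost under 4 or 5 of the 8 alternatives. Histones had peaks at 10 of 72 genes (13.9%, adjusted exact p = 0.0315), led by his-37 (351), the shared peak of his-67 and his-68 (219) and his-31 (95.7), but replicate 1 alone gave 8.33% (adjusted exact p = 0.44, range over settings 0.00112 to 1), and the call also ended among the stronger peaks, with each peak given to the nearest gene and with shared promoters left out (odds ratio 0.877). Body wall muscle genes stood at 6 of 35 (17.1%, adjusted exact p = 0.0424), among them unc-60 (96.3), act-4 (79.6), pat-6 (68.5) and unc-112 (66.8), and replicate 1 alone gave 14.3% (adjusted exact p = 0.0887, range 0.0205 to 1), with the call also lost among the stronger peaks, with the nearest gene and in both other promoter windows (odds ratio 0.786 in the narrow one). The heterochronic genes, which time larval development, stood at 4 of 16 (25%, adjusted exact p = 0.0352). Of these, nhl-2 shared the strong peak upstream of tag-340 (399), while lin-46 (53.6), lin-28 (52.5) and lin-14 (49.9) lay near the threshold, and replicate 2 alone gave 12.5% (adjusted exact p = 0.406, range 6.61e-05 to 0.696), with the call also lost among the stronger peaks, in the narrow window and with shared promoters left out. In replicate 2 no summit lay within 100 bp of those of lin-28 and lin-14, and the lin-14 peak ranked 4470 in replicate 1.

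Chemoreceptor genes, mostly used in single sensory neurons, were nearly free of peaks. Only 4 of 1310 carried a promoter peak (0.305%, 0.0833 to 0.780, odds ratio 0.0442, adjusted exact p = 1.35e-29), namely srh-269 (100.3), sri-5 (98.9), srh-16 (79.3) and srh-2 (53.7). That odds ratio ran from 0.0219 with shared promoters left out to 0.103 with the nearest gene. C-type lectins had 1 of 240 (clec-126, signal 84.7, adjusted exact p = 4.84e-05) and cytochromes P450 with conjugating enzymes 1 of 185 (gst-27, signal 68.6, adjusted exact p = 0.000848). The latter did not pass with shared promoters left out (adjusted exact p = 0.0988, range over settings 0.000848 to 0.0988). With replicate 2 alone the shares of these 2 lists were 0.833% and 1.08%, against 0.417% and 0.541%, and over settings their odds ratios ran from 0.0464 to 0.2002 and from 0 to 0.247. No promoter peak was found at 31 major sperm protein genes, 30 intestinal, 37 cilia, 21 pharyngeal or 14 glial genes, but lists of these sizes with a count of 0 allow shares of up to 9.68%, 10%, 8.11%, 14.3% and 21.4%, and none passed the test (adjusted exact p = 0.346, 0.346, 0.291, 0.693 and 1). Cilia genes stood at 2.70% with either replicate alone.

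The remaining lists did not pass either, at adjusted p from 0.0676 upward. Vacuolar ATPase subunits (4 of 20, adjusted exact p = 0.0676) and mitochondrial ribosomal proteins (9 of 70, adjusted exact p = 0.0753) came nearest, and both passed with each replicate alone (vacuolar ATPase 0.0118 and 0.014, mitochondrial ribosome 0.0376 and 0.0208 for replicates 1 and 2, ranges over settings 0.0118 to 0.322 and 0.0208 to 0.7). Their strongest peaks were at vha-8 (110) and mrpl-28 (176). Pan-neuronal genes had 5 of 30 (adjusted exact p = 0.0696), with unc-108 (123) highest, and passed with each peak given to the nearest gene (adjusted exact p = 6.61e-05), with the wide promoter window (0.0014) and with shared promoters left out (0.0117), in a range over settings of 6.61e-05 to 0.504. Nuclear hormone receptors had 18 of 269 (adjusted exact p = 0.684), with strong peaks at nhr-68 (211) and nhr-49 (169), but replicate 1 alone gave 4.09% against 6.69%, and the odds ratio turned from 1.11 to 0.726 there and to 0.4003 in the narrow window. Neuropeptides and insulins had 3 of 141 (adjusted exact p = 0.0939, ins-39 at 227) and cuticle collagens 5 genes or 2.86% (adjusted exact p = 0.142, col-38 at 77.7). With replicate 2 alone both of the last lists, then at 0.709% and 1.14%, passed as lower (adjusted exact p = 0.00938 and 0.00668, ranges 0.00938 to 0.385 and 0.00668 to 0.5). Aminoacyl-tRNA synthetases had 3 of 31, ztf genes 1 of 25 (ztf-7, signal 205), homeobox genes 2 of 91 (ceh-38 at 190 and ceh-20 at 70.0), bHLH genes 3 of 36 and fatty acid enzymes 2 of 69. Epidermal genes had 3 of 29, neuron identity factors 1 of 30, germline genes 3 of 36, and insulin and dauer signalling and Wnt signalling genes 3 of 27 each. For these 10 lists the adjusted exact p lay between 0.295 and 1, but the insulin and dauer list passed with each peak given to the nearest gene (adjusted exact p = 0.00264, range over settings 0.00264 to 1). Replicate 2 alone gave 3.23% for synthetases (9.68% in the IDR peaks), 7.25% for fatty acid enzymes (2.90%), 6.90% for epidermal genes (10.3%) and 7.41% for the insulin and Wnt lists (11.1%), and replicate 1 alone 12.9% for synthetases, 6.90% for epidermal genes and 8% for ztf genes (4%). The odds ratio fell on both sides of 1 over settings for synthetases (0 to 2.54), ztf (0 to 1.63), bHLH (0.764 to 2.39), fatty acid (0.392 to 1.35), epidermal (0 to 3.55), neuron identity (0.387 to 1.06) and germline genes (0.764 to 2.80).

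**Figure D3:**
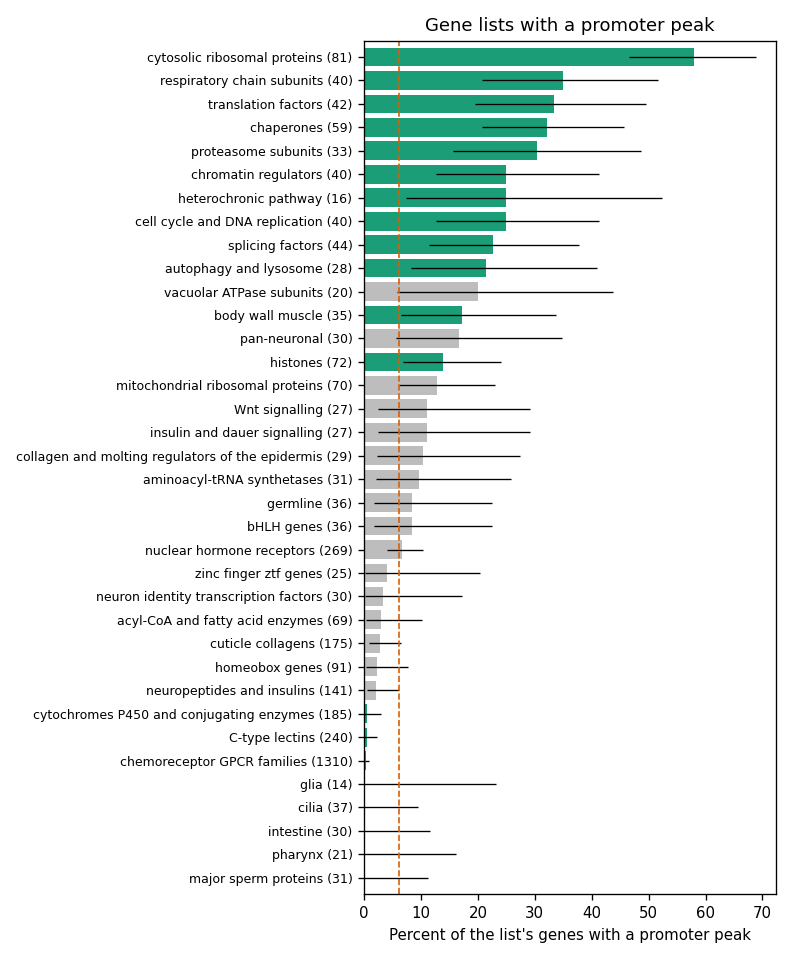
Percent of each list's genes with a promoter peak, with exact 95% intervals and the number of genes in parentheses, for the 36 gene lists. Green bars passed Fisher's exact test at an adjusted p under 0.05, grey bars did not, and the dashed line marks the 6.07% over all protein-coding genes. Cytosolic ribosomal proteins reach 58.0%, and chemoreceptor genes stand at 0.305%.

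The tagged gene carried no peak of its own. The ztf-4 gene (WBGene00020399, I:6926257-6929665) had no region within 1000 bp in any of the ce11 lists, and its nearest IDR summit lay 90673 bp away. Within 20000 bp of the gene the pooled relaxed list held 2 regions, while random windows of the same size held a median of 9 (95% of windows 1 to 25). The list of replicate 1 held 1 region there, just below its range (median 11.5, 1.975 to 27). That of replicate 2 held 3, within its range (median 11, 2 to 28.025). The strain carries the tagged ztf-4 as an extra copy. How reads from that copy affect calls at the native gene was not examined, so the missing peak need not mean absent recovery. The unc-119 gene (WBGene00006843, III:10902641-10908935), which is mutated in the strain, had an IDR peak at III:10903233-10903582 in an intron, 767 bp downstream of its 5' end. Its pooled signal of 71.8 gave rank 969, with rank 2165 in replicate 1 and 580 in replicate 2.

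Genes of small structural RNAs lay near peaks more often than shifted summits would give. Summits lay within 200 bp of 56 of 346 snoRNA genes (16.19%), against a mean of 3.589 (SD 1.87) after shifting, a 15.6-fold excess. The corresponding counts were 14 of 129 snRNA genes (11.7-fold), 50 of 612 tRNA genes (8.83-fold) and 391 of 7764 genes annotated as other ncRNA (4.84-fold), all at an adjusted permutation p of 0.002, the smallest reached. Long intergenic RNAs (14 of 194, 2.48-fold, adjusted permutation p = 0.002) and microRNAs (8 of 261, 3.18-fold, adjusted permutation p = 0.02) also passed, but not when the summit had to lie inside the gene (adjusted permutation p = 0.12 and 0.56), where the excess of other ncRNA was 7.68-fold, and that of snRNA genes was 20.5-fold among the stronger peaks. All 6 classes also passed with each replicate alone, where the excess of snoRNA genes was 14.2-fold and 15.3-fold and that of tRNA genes 9.37-fold and 9.56-fold. Of the 56 snoRNA genes, 27 lay inside protein-coding genes and 20 shared a peak with a promoter window. Such sharing was seen for 8 of the 14 snRNA genes, 8 of the 14 long intergenic RNAs and 1 of the 8 microRNAs. It held for 9 of the 50 tRNA genes, which rested on 43 distinct peaks. Antisense RNAs did not pass (4 of 100, adjusted permutation p = 0.3). Of 15363 piRNA genes 17 and of 2128 pseudogenes 9 lay near a peak, against 111.99 and 63.7 after shifting, in a test that looks for excess only, and 0 of 20 rRNA genes did, which allows up to 15%. Whether reads could be placed uniquely at the rRNA genes was not examined.

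Summits were rich in C and G, and 6-mers around the core ACGC were the most frequent of those named. The 101 bp at the summits held 46.4% GC (SD 7.85 over 1898 windows), against 35.6% (SD 8.42 and 8.40) on each side. Of the 2080 6-mers, 521 were more frequent and 369 less frequent at summits than on both sides by the exact McNemar test at an adjusted p under 0.05. GACGCA was present at 17.8% of summits against 2.13% beside them (ratio 8.35, adjusted exact p = 6.87e-61), ACGCAG at 17.3% against 1.90% (9.14, adjusted exact p = 2.19e-60) and AGACGC at 15.4% against 1.92% (8, adjusted exact p = 7.07e-51). GCGCGC reached 6.74% against 0.711% (9.48, adjusted exact p = 7.98e-21) and CGCGCC 7.96% against 1.16% (6.86, adjusted exact p = 3.86e-23). All 5 also passed with each replicate alone, where the ratio of ACGCAG was 6.76 in replicate 1 and 8.50 in replicate 2. Among the 474 strongest peaks 23.4% (19.7 to 27.5) held ACGCAG, and among the 474 weakest 13.1% (10.2 to 16.5), a difference that was not tested. Against windows of unbound promoters matched on GC content, a background chosen after the data were seen, 229 6-mers were more frequent and 337 less frequent, and the 5 ratios fell to between 1.78 and 3.83. Within 25 bp of the summit the ratios of GACGCA and AGACGC were 12.8 and 12.1.

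**Figure D4:**
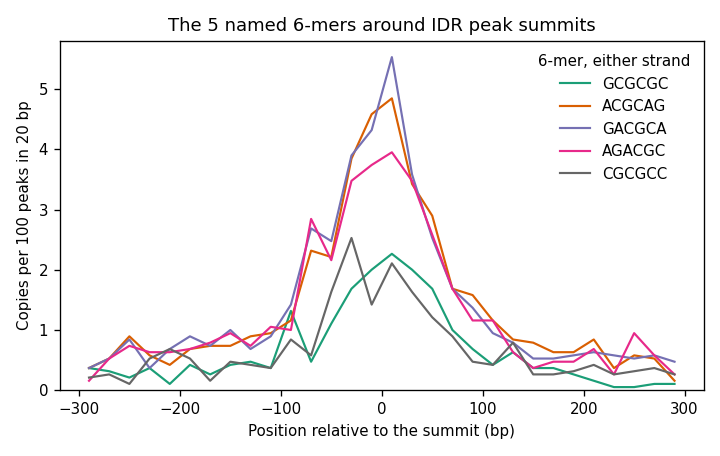
Copies of the 5 named 6-mers, on either strand, per 100 IDR peaks in bins of 20 bp by distance from the summit in bp. All 5 lines peak near the summit and fall to low levels on both sides.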

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

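The relaxed pooled list goes on below the IDR threshold, in data that no comparison between gene groups used. Of the 1898 regions ranked 1899 to 3796, 38.4% (36.2 to 40.6) had their summit in a promoter window, against 21.3% (SD 1.02) for shifted summits, a share chosen for a look after the data were seen (1-sided permutation p = 0.005, the smallest that 200 shifts allow). Of these regions 76.3% had a match in both relaxed replicate lists. The promoter share was 32.2% at ranks 3797 to 5694 and 26.4% at ranks 7593 to 9490.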

How the results depend on the processing

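A value counted as kept if it stayed on its side of the threshold, within 1.5 times for counts. A replicate correlation counted as kept within the bootstrap interval of its main value. Of 49 alternative values for the main results, 45 were kept. In 6 of them, however, the strongest regions of the pooled list replaced the IDR peaks, which are the same regions, so those say nothing, nor do 51 such values among those for single lists, RNA classes and 6-mers. With each replicate alone the promoter share ranged from 45.6% to 49.4%, the X share from 17.7% to 18.8%, the difference in log2 signal from 0.13 to 0.17, the number of gene lists called from 15 to 18, and the number of 6-mers from 436 to 514. The exceptions were the X share of 18.9%, which did not differ from the X share of genome length (exact p = 0.157), the signal difference of 0.0428 among the 949 stronger peaks (permutation p = 0.357), the count of gene lists, which fell from 15 to 9 with shared promoters left out, and the count of 6-mers, which fell from 521 to 229, with 337 lower, against GC-matched windows, an alternative chosen after the data were seen. With shared promoters left out fewer peaks are tested, and the stronger peaks were picked by the very signal compared, which can narrow the difference. For the X share and the 6-mers the cause was not tested. The odds ratio reversed for histones with shared promoters left out (0.877) and for body wall muscle in the narrow promoter window (0.786), and the cause was not tested. Of 373 alternative values for single lists, RNA classes and named 6-mers, 340 kept their side, 21 lost their call, 10 gained a call and 2 reversed. The files give no depth, so whether more reads would add peaks at the lists near the threshold is open.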

Other observations

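Spliced leader RNA genes were singled out after their values were seen. The 5 with a peak are among the 14 snRNA genes already counted above, so they are not further sites. SL2 RNAs provide the leader that is spliced onto downstream genes of worm operons. Of 18 genes named sls-2, 5 (27.8%, 9.69 to 53.5) had an IDR summit within 200 bp, namely sls-2.4 on I (signal 469, rank 11), sls-2.2 on II (398, rank 20), sls-2.1 on II (348, rank 28), sls-2.8 on III (182, rank 135) and sls-2.3 on II (63.5, rank 1196). Of 12 genes named sls-1, the source of the other leader, 0 had one, which allows up to 25%. Whether reads could be placed uniquely at the sls-1 genes was not examined, so the 0 need not mean absent recovery.

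In the weighing that follows, the tests were chosen after the main results were seen, apart from the comparison of 6-mers with windows at the same distances from unbound genes, which was among the alternatives fixed beforehand. For X, the tRNA genes and the housekeeping lists the tested values, or close relatives of them, had been seen as well.

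Of the 50 strongest peaks outside promoter windows, 19 lay on X (38%, 24.7 to 52.8), against 21.7% of all such peaks, and of the 50 strongest promoter peaks 6 did, a pattern noticed in these same peaks. A higher recovery over the whole X stays open: with the 20 strongest peaks left out, the 90th percentile of log2 signal on X minus that on autosomes was −0.15 in promoters (bootstrap interval −0.48 to 0.18), so no higher signal was detected there, while the difference outside minus that inside promoters, 0.34, had an interval of −0.10 to 0.77 that includes 0. TCGCGCAGGGAG, a motif known from sites that recruit the dosage compensation complex to X, matched with at least 11 of 12 bases in the 350 bp around the summit in 11 of 209 X peaks and 0 of 753 autosomal peaks outside promoters, where a count of 0 allows 0.398% (Fisher's exact p = 4.12e-08). Of its 32 matches on X 16 had a summit that near, and of its 37 on autosomes 0, which allows 8.11% (Fisher's exact p = 3.14e-07). The 11 matching X peaks outside promoters had pooled ranks 8, 12, 15, 17, 24, 27, 35, 39, 54, 188 and 377. Those of rank 12 (X:8036294-8036540) and 377 (X:8036551-8036638) are neighbours with overlapping windows, so they need not be separate sites. The peak of rank 377 is also counted above as near a tRNA gene. The X peaks of rank 13 and 18 outside promoters had no match. In promoters, 2 of 150 X peaks matched, nearest to nspc-17 (rank 10) and R04E5.9 (rank 798). A candidate explanation for part of the pattern is recovery at recruitment sites of that complex, and it stays open whether the tagged protein or the procedure itself brings it about, since no mock precipitation was analysed here.

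The 9 lists of general cell machinery, grouped by function whether or not they passed, hold 420 genes of which 130 carried promoter peaks (odds ratio 7.65, 6.16 to 9.49), while chemoreceptor genes rarely did (odds ratio 0.0442). With genes compared within 10 equal parts of each chromosome the Mantel-Haenszel odds ratios were 6.42 (5.14 to 8.003) and 0.0600 (0.0221 to 0.163), which argues against position along the chromosome as the whole cause. Within 10 classes of promoter GC content they were 6.55 (5.25 to 8.18) and 0.0591 (0.0220 to 0.159), which argues against GC content in the same way. Recovery at strongly transcribed genes whichever protein is tagged may contribute. The tRNA genes, which another polymerase transcribes, lay near summits 8.83 times as often as after shifting. That value was known beforehand and would also arise if ZTF-4 itself lay there, so it cannot decide. Transcription was not measured here. Such recovery stays open, because no mock precipitation and no other tagged factor was analysed here, and no biological explanation was tested.

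The 6-mers called at summits could follow from base composition or from the distance to genes. To avoid testing them on the peaks that picked them, the 287 6-mers called on odd-ranked peaks were measured on the 949 even-ranked ones. Their median share was 1.503 times (1.44 to 1.58) that in GC-matched windows of unbound promoters and 3.03 times (2.85 to 3.22) that in windows at the same distances from unbound genes. The first value argues against total GC content as the whole cause, although only 182 of the 521 calls were also made against the GC-matched windows. Composition beyond total GC content was not matched, so it stays open. The second argues against distance to genes alone as the whole cause. Its windows held 34.9% GC against 46.4% at summits, however, so that ratio mixes position with GC content. Whether the remainder reflects sequence that ZTF-4 itself recognises was not tested.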
